A study of Mus musculus with 8 samples.

How the data were processed

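Single-cell RNA was measured in CD45+ cells sorted from MC38 tumours of wild-type mice, in 2 control and 2 LNP-Sirpa cDNA libraries. The labels name a DNBelab C Series droplet kit, polyA RNA, sequencing on a DNBSEQ-T7 and 1 batch for all libraries. According to the submitters' processing notes, reads were aligned with STAR 2.5.1b to GRCm39. The deposited matrices hold whole-number UMI counts per gene and cell, written by PISA 1.0 per the file headers. The rule that called cells and the gene annotation are not given in the sources used here, and genes carry symbols only. The 4 oligo libraries of the same samples were not analysed here.

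The 4 matrices held 7511, 10890, 10348 and 9008 barcodes, each with at least 1000 UMIs, and 24129, 24884, 25032 and 23759 genes, 27405 in their union; a gene that a library did not list was counted as 0. Cells needed at least 500 UMIs, 300 genes and at most 15% mitochondrial UMIs, and 7, 14, 16 and 3 failed. Scrublet in scanpy 1.11.5 marked 4, 0, 1 and 0 cells at its automatic threshold, under the 0.5% set as a minimum, so the cells with the highest scores were left out instead, 340, 467, 438 and 428 cells or 4.53%, 4.29%, 4.24% and 4.75%. Counts per 10000 were log transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2, igraph 0.11.9) at resolution 2 gave 40 clusters, without integration of libraries. Work in Python 3.11.15 also used numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.

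Clusters were named from fixed marker lists. The marker lists, gene lists, cell filters, tests and the rule for named genes were set before the data were examined. The thresholds of the naming were set after: a list score of at least 0.25, a subset ratio of 1.5 and at least 3 own markers detected. Clusters stayed unnamed where the lower of their phagocyte and lymphocyte scores reached 0.4 of the higher at a doublet score 1.7 times the usual, or where another list had more markers among the 10 top genes by fold (10 CPM added). CPM are counts scaled to equal library totals. A class entered a test where every library held at least 20 of its cells. UMI counts were summed per library and class, which gave from 31132937 to 45744517 UMIs for monocyte/macrophage-like, 982544 to 4649529 for dendritic-like, 92283 to 1277160 for neutrophil-like, 491789 to 3058733 for CD8 T-like, 642133 to 2334530 for regulatory T-like and 840933 to 6475625 for NK-like sums.

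LNP-Sirpa was tested against control with edgeR 4.0.16 in R 4.3.3 (TMM, filterByExpr, robust quasi-likelihood fit and F test) with Benjamini-Hochberg adjustment over the genes of a class and a threshold of 0.05. Gene lists were tested with camera (limma 3.58.1) at its preset correlation of 0.01, adjusted over the lists of a class, and beside it with an estimated correlation and with fry. A member count "adjusted over the list alone" used the same gene p-values adjusted within the list. Numbers of cells per class were tested with edgeR with all kept cells as library size, and shares and the ratio of CD8 T-like to regulatory T-like cells with an exact permutation test, whose smallest p was 0.3333. The interaction of treatment and class was tested with edgeR over the sums of phagocytes and of all T and NK classes, with the library as a block.

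Named genes followed a rule. Sirpa and Cd47 were named in every class, and in monocyte/macrophage-like cells the 10 largest rises and 10 largest falls past the threshold with a mean of at least 50 CPM (5 and 5 in other classes). Up to 4 members per fixed list with the smallest p among those past the threshold were added. Predicted genes, ribosomal and mitochondrial genes and receptor segments were left out. Not every gene chosen by the rule is given in the text. Named genes without a UMI in the controls were given only as a bound against 3 counts over the group. Intervals of cell shares are 95% Wilson intervals.

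On simulated data made from the same sums with 200 changed genes, edgeR recovered 43% of genes at log2 1 and 90.9% at log2 2 in monocyte/macrophage-like cells, 48.5% and 88.7% in dendritic-like, 9.8% and 65.5% in neutrophil-like, 29.9% and 89.5% in CD8 T-like, 35.1% and 92.7% in regulatory T-like and 40.2% and 95.7% in NK-like cells, with at most 8 unchanged genes called in a class. None of 30 random lists passed in any class. Simulated genes were drawn independently of each other, so this does not show how the list test behaves where genes move together. The estimated correlation of the type I interferon list in monocyte/macrophage-like cells was 0.94. The interaction test recovered 53.6% and 65.7%.

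The alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, each library left out in turn, the replicate number as a block, doublets kept, a stricter cell filter (1000 UMIs, 500 genes, 10% mitochondrial), resolutions 1 and 3, macrophage-like or monocyte-like clusters alone and sums thinned to the smallest total. For shares, TMM over classes and named immune cells as denominator were also run. With a library left out, the lone library of its group was assumed to vary like the other group. Alternatives added after the data were seen were unnamed phagocyte clusters added, clusters under 0.7 of the usual UMI count left out, a cluster with over 90% of its cells from 1 library left out, the cDC2-like cluster alone, and subtraction of the phagocyte profile of the same library, scaled by the median ratio of macrophage markers, at 25%, 50%, 75% and 100%. For a test of cell shifts, folds were taken from mean CPM plus 1 inside phagocyte clusters with at least 20 cells of every library, for lower genes with as many genes as were called, picked by the largest fall between 2 libraries. The reference at hand was of another genome build, so no coordinates were used.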

Results

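Droplet single-cell RNA sequencing measured transcripts of CD45+ cells sorted from MC38 tumours, which arise from a mouse colon carcinoma line, in wild-type mice. There were 2 control libraries and 2 libraries from tumours after LNP-Sirpa treatment, which the series title describes as degradation of SIRPα directed at the tumour. SIRPα, encoded by Sirpa, is an inhibitory receptor of phagocytes, and its ligand CD47 protects cells from being engulfed. The comparison asks how macrophages and other immune cells of the tumour differ after the treatment. The labels do not say what the controls received, so it does not separate Sirpa targeting from other effects of the treatment. Control replicates 1 and 2 held 68654004 and 90789729 unique molecular identifiers (UMIs), and LNP-Sirpa replicates 1 and 2 held 85810250 and 70581678. After filtering, 7164, 10409, 9894 and 8577 cells were kept in the same order, with a median of 6767, 6358, 5756 and 5815 UMIs per cell. The labels do not say that the replicates came from separate animals, so the p-values measure only the spread between these samples, which may be technical. Fold changes below are log2 values of LNP-Sirpa over control, each with its SE, from edgeR on counts summed per library and class (n = 2 libraries per group).

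Cells of 18 clusters carried macrophage or monocyte markers and were compared as monocyte/macrophage-like cells, 5057 and 6581 in the control libraries and 4711 and 5256 in the LNP-Sirpa libraries. The class was spread over different clusters in the 2 groups. The 6 clusters largest in control (1, 4, 5, 11, 12 and 14) held 66.3% of its control and 8.5% of its LNP-Sirpa cells. The 6 largest in LNP-Sirpa (2, 3, 8, 15, 16 and 22) held 7.4% and 69.1%. LNP-Sirpa replicates 1 and 2 held 1458 and 300 cells in cluster 2 and 70 and 582 in cluster 22. A threshold set after the data were seen kept mixed phagocyte and lymphocyte clusters out of the classes. These made up 2.62% and 7.24% of kept cells in the control libraries and 12.9% and 6.95% in the LNP-Sirpa libraries. Phagocyte clusters left unnamed by the same kind of threshold made up 5.40%, 9.12%, 2.64% and 11.9% in that order, and clusters in which no marker list reached the minimum 2.92%, 2.35%, 2.10% and 2.36%.

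Sirpa RNA, the transcript of the targeted gene, did not pass the test in any class. In monocyte/macrophage-like cells it stood at 585 ± 1.94 CPM (counts scaled to equal library totals; SD, n = 2) in control and 417 ± 123 CPM in LNP-Sirpa libraries, with 583, 586, 504 and 330.2 CPM in the single libraries (log2 -0.33 ± 0.23 SE, adjusted p = 0.478). The value was -0.52 (adjusted p = 0.0651) without LNP-Sirpa replicate 1, -0.17 (adjusted p = 0.534) without LNP-Sirpa replicate 2 and 0.07 (adjusted p = 0.925) in monocyte-like clusters alone. The other classes gave -0.24 (dendritic-like), -0.30 (neutrophil-like), -0.89 (CD8 T-like), -0.42 (regulatory T-like) and -0.79 (NK-like), with adjusted p from 0.110 to 0.786. Leaving out LNP-Sirpa replicate 1 or 2 moved the dendritic-like value to -0.37 and -0.12, and leaving out control replicate 1 or LNP-Sirpa replicate 1 moved the neutrophil-like value to -0.13 and -0.19. The CD8 T-like value passed without LNP-Sirpa replicate 1 (-1.02, adjusted p = 0.0168) and at the higher cluster resolution (-1.11, adjusted p = 0.0278). The NK-like value passed without control replicate 1 (-1.03, adjusted p = 0.0390). It was -0.53 (adjusted p = 0.895) without control replicate 2, -1.33 (adjusted p = 0.0782) without LNP-Sirpa replicate 1 and -0.50 (adjusted p = 0.390) without LNP-Sirpa replicate 2.

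Sirpa UMIs were also present in T/NK-like cells, which should lack the receptor and so show the background of free RNA. At least 1 Sirpa UMI was found in 89.4% (95% Wilson interval 88.5 to 90.2) and 88.0% (87.2 to 88.8) of control monocyte/macrophage-like cells and in 81.1% (80.0 to 82.2) and 77.9% (76.8 to 79.0) of LNP-Sirpa ones, at median depths of 6211, 5660, 5081 and 6492 UMIs. In T/NK-like cells the shares were 49.9% (45.9 to 53.9) and 44.5% (41.5 to 47.6) in control and 30.6% (28.7 to 32.6) and 20.2% (17.9 to 22.7) in LNP-Sirpa libraries, at 6759, 5633, 5023 and 3603 UMIs. After each cell was thinned to 2000 UMIs, the phagocyte shares were 65.2% (63.7 to 66.6), 62.2% (60.9 to 63.5), 57.4% (55.8 to 59.0) and 46.4% (44.9 to 47.8), and the T/NK-like shares 20.5% (17.3 to 24.1), 19.8% (17.3 to 22.6), 14.3% (12.7 to 16.0) and 10.4% (8.51 to 12.6). Thinning left out 933, 1139, 1024 and 762 phagocytes and 43, 118, 294 and 216 T/NK-like cells as too shallow. The intervals cover counting error only.

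Cd47 lay at the threshold. Its level in monocyte/macrophage-like cells was 161 ± 2.94 CPM in control and 285 ± 94.8 CPM in LNP-Sirpa libraries (SD, n = 2; log2 0.97 ± 0.22 SE, adjusted p = 0.0508). It passed without LNP-Sirpa replicate 1 (0.74, adjusted p = 0.0124), without LNP-Sirpa replicate 2 (1.17, adjusted p = 0.00104) and with DESeq2 (0.99, adjusted p = 4.19e-04). The dendritic-like value of 0.76 ± 0.20 (adjusted p = 0.0572) passed without LNP-Sirpa replicate 2 (0.91, adjusted p = 0.00105) and with DESeq2 (adjusted p = 0.0478). Values in the remaining classes were 1.10 ± 0.36 (neutrophil-like), 0.63 ± 0.19 (CD8 T-like), 0.67 ± 0.20 (regulatory T-like) and 0.69 ± 0.20 (NK-like), with adjusted p from 0.150 to 0.210. Of these, the CD8 T-like and regulatory T-like values passed without LNP-Sirpa replicate 2 (0.71 and 0.80, adjusted p = 0.0364 and 0.0115).

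In monocyte/macrophage-like cells Nos2, the inducible nitric oxide synthase, rose from 12.5 ± 5.23 to 142 ± 35.2 CPM (SD, n = 2; log2 3.66 ± 0.34 SE, adjusted p = 0.00766). Inhba, a subunit of activin A, rose by 3.55 ± 0.25, Upp1, which cleaves uridine, by 3.45 ± 0.26 and Ltb4r1, a leukotriene B4 receptor, by 3.28 ± 0.35 (adjusted p = 0.00303, 0.00358 and 0.0116). Arg1, the arginase that consumes arginine, rose from 1395 ± 201 to 4783 ± 1898 CPM (log2 1.99 ± 0.43, adjusted p = 0.0457). The PD-1 ligand genes Cd274 and Pdcd1lg2 rose by 1.99 ± 0.34 and 2.81 ± 0.28 (adjusted p = 0.0287 and 0.00745). Selenop, a selenium carrier, fell from 523 ± 136 to 128 ± 43.1 CPM (log2 -1.89 ± 0.29, adjusted p = 0.0192). Folr2, a folate receptor, fell by 1.74 ± 0.26 and Stab1, a scavenger receptor, by 1.54 ± 0.26 (adjusted p = 0.0186 and 0.0248).

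In all, 763 of 15574 genes tested changed in monocyte/macrophage-like cells, 541 higher and 222 lower. Among the 10 largest rises were also the interferon-induced Oasl1 (3.61 ± 0.49), Isg15 (3.21 ± 0.51) and Ifitm1 (3.24 ± 0.28), and Ly6i (4.78 ± 0.31), Ly6a (4.06 ± 0.41) and Ly6c2 (3.82 ± 0.45) of the Ly6 surface protein family (adjusted p from 0.00303 to 0.0265). The Ly6, Ifitm and Oasl families have near-identical members whose reads the counting could split, so single members are uncertain. The largest falls also took in Igfbp4 (-2.16 ± 0.21), F13a1 (-1.54 ± 0.24), Slc9a9 (-1.45 ± 0.29), Gpr183 (-1.39 ± 0.18), Syngr1 (-1.34 ± 0.24), Pmp22 (-1.31 ± 0.22) and Lyz1 (-1.31 ± 0.27), with adjusted p from 0.00741 to 0.0436. Lyz1 shares sequence with Lyz2, and Ly6c2, F13a1, Arg1 and Igfbp4 here, and Chil3, Ms4a4c, Retnlg, Cd200, Bst2 and Gzma below, were also among the markers used to name the clusters. DESeq2 gave 1398 changed genes, macrophage-like clusters alone 230 and monocyte-like clusters alone 246. Leaving out control replicate 1, control replicate 2, LNP-Sirpa replicate 1 or LNP-Sirpa replicate 2 gave 465, 470, 1803 and 2032. Of the 57 genes chosen by the rule, 20 did not pass without control replicate 1 (adjusted p from 0.0509 to 0.425), among them Arg1 (1.82, adjusted p = 0.275) and Lyz1 (-1.09, adjusted p = 0.0709). A further fit without control replicate 2 also lost 20 (adjusted p from 0.0564 to 0.228), among them Arg1 (2.21, adjusted p = 0.218), Stab1 (-1.60, adjusted p = 0.0564), Slc9a9 (-1.39, adjusted p = 0.0651), Pmp22 (-1.22, adjusted p = 0.0759) and Syngr1 (-0.98, adjusted p = 0.0917). Without LNP-Sirpa replicate 1, 7 did not pass, among them Nos2 (3.52, adjusted p = 0.0791), Cd274 (1.88, adjusted p = 0.231), Ly6a (4.03, adjusted p = 0.105), Ly6c2 (3.36, adjusted p = 0.119) and Syngr1 (-1.17, adjusted p = 0.0784). Without LNP-Sirpa replicate 2, 9 did not, among them Nos2 (3.77, adjusted p = 0.0791), Cd274 (2.09, adjusted p = 0.194), Ltb4r1 (2.97, adjusted p = 0.0763), Ly6a (4.09, adjusted p = 0.113) and Ly6c2 (4.17, adjusted p = 0.0915).

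**Figure D1:**
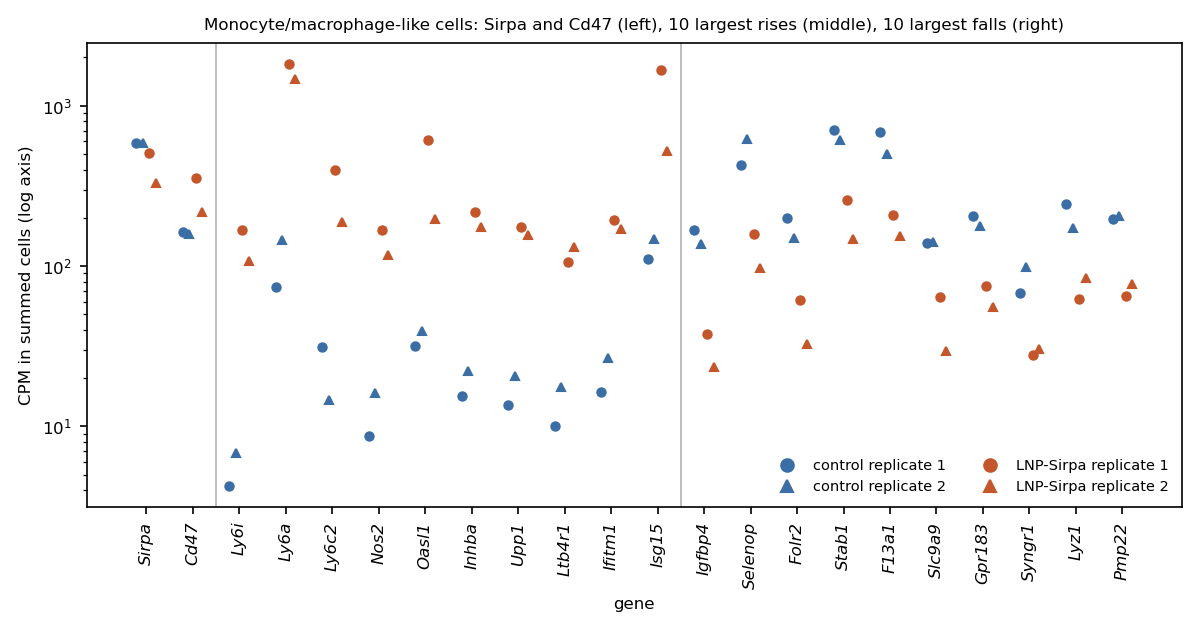
CPM on a log axis of Sirpa, Cd47 and the 10 largest rises and 10 largest falls among changed genes in monocyte/macrophage-like cells, with 1 point per library, colour for the group and marker shape for the replicate. Nos2 lies at 8.76 and 16.2 CPM in the control libraries and at 167 and 117 CPM in the LNP-Sirpa libraries, while Sirpa lies at 583, 586, 504 and 330.2 CPM.

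Interferon-induced genes rose together in monocyte/macrophage-like cells. Of 26 measured members of the type I interferon list, 14 rose and none fell (25 rose and 0 fell when adjusted over the list alone). Among them were the antiviral Rsad2 (3.02 ± 0.42), the nucleic acid sensor Zbp1 (2.37 ± 0.28) and Ifi205 (3.50 ± 0.32), with adjusted p from 0.00745 to 0.0200. The list's median was 2.42 (camera, adjusted p = 6.74e-36; adjusted p = 0.358 with an estimated correlation). In the interferon gamma list 12 of 23 members rose (20 adjusted over the list alone; median 1.66, adjusted p = 3.49e-25). The chemokine Cxcl10 rose from 199 ± 48.7 to 646 ± 51.0 CPM (SD, n = 2; log2 1.86 ± 0.27), as did Socs1, an inhibitor of cytokine signalling (1.73 ± 0.23), and Batf2 (1.44 ± 0.18). MHC class I genes rose in 6 of 14 cases (11 adjusted over the list alone; median 0.98, adjusted p = 1.62e-11), with H2-T23 at 1.95 ± 0.25, the immunoproteasome subunit Psmb9 at 1.04 ± 0.20 and the peptide transporter subunit Tap2 at 1.02 ± 0.22. The inflammatory macrophage list had 5 of 14 members higher (9 adjusted over the list alone; median 1.09, adjusted p = 6.91e-13), namely Nos2, Cxcl10, Il6 (2.03 ± 0.28), the cyclooxygenase gene Ptgs2 (2.08 ± 0.30) and, named after its values were seen, the costimulatory Cd80 (0.94 ± 0.19). These 3 lists too gave adjusted p = 0.358 with an estimated correlation. Psmb9 and Tap2 did not pass without control replicate 1 (adjusted p = 0.229 and 0.0741) or 2 (0.131 and 0.128), Cxcl10 without control replicate 1 (1.60, adjusted p = 0.0675) and Ptgs2 without LNP-Sirpa replicate 1 (2.29, adjusted p = 0.0575) or 2 (1.83, adjusted p = 0.0993). Without control replicate 2 the inflammatory list's median was 1.71.

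Of 22 genes of the cell cycle, 3 were lower in monocyte/macrophage-like cells. Mki67, a marker of proliferation, fell from 151 ± 24.3 to 67.3 ± 6.79 CPM (SD, n = 2; log2 -0.99 ± 0.18, adjusted p = 0.0307), and the mitotic genes Cenpf and Nusap1 by 0.84 ± 0.17 and 0.74 ± 0.16 (adjusted p = 0.0398 and 0.0442). These were the 3 of 22 members that passed (12 adjusted over the list alone; median -0.69, adjusted p = 5.47e-09; adjusted p = 0.505 with an estimated correlation). Of these, Cenpf, Mki67 and Nusap1 did not pass without control replicate 1 (adjusted p = 0.273, 0.170 and 0.260) or control replicate 2 (0.0676, 0.0822 and 0.178), and the median was -0.45 without LNP-Sirpa replicate 1. It was also -0.45 in macrophage-like clusters alone, and 0.22 (adjusted p = 0.138) in monocyte-like clusters alone.

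Matrix, glycolysis and chemokine genes were higher as lists, with few single members past the threshold. In the glycolysis and hypoxia list (median 0.57, adjusted p = 5.77e-05) 3 of 22 members rose (3 adjusted over the list alone): the phosphofructokinase Pfkp (1.11 ± 0.19), the growth factor Vegfa (1.46 ± 0.27) and Ero1a (1.02 ± 0.21), which oxidises proteins in the endoplasmic reticulum. In the matrix remodelling list (median 0.71, adjusted p = 0.0118) the protease Mmp19 (1.46 ± 0.15), the protease inhibitor Timp1 (1.53 ± 0.19) and Adam8 (1.11 ± 0.24) were the 3 of 13 that rose (7 higher and 3 lower adjusted over the list alone). Cxcl3 (2.27 ± 0.29) and Cxcl10 rose among 18 myeloid chemokines (2 adjusted over the list alone; median 0.42, adjusted p = 1.76e-04). Traf1 (1.21 ± 0.19) and Sod2 (1.01 ± 0.22) rose among 20 NF-kB and TNF response genes (2 adjusted over the list alone; median 0.43, adjusted p = 3.41e-04). With an estimated correlation the adjusted p were 0.524 for glycolysis and NF-kB and 0.358 for matrix and chemokines. The glycolysis median was 0.88 without LNP-Sirpa replicate 1 and 0.15 (adjusted p = 0.317) without LNP-Sirpa replicate 2, and the matrix list did not pass without control replicate 2 (0.74, adjusted p = 0.0583) or without clusters of low UMI counts (0.62, adjusted p = 0.0641). The NF-kB median was 0.27 without control replicate 1 and 0.74 without control replicate 2, and the chemokine median 0.63 without control replicate 2 and 0.17 without LNP-Sirpa replicate 2. Single genes were lost without control replicate 1 (Pfkp, Ero1a, Adam8, Traf1 and Sod2, adjusted p from 0.0778 to 0.382), without control replicate 2 (Pfkp, Ero1a, Adam8 and Sod2, adjusted p from 0.0741 to 0.228) and without LNP-Sirpa replicate 2 (Vegfa 1.19, adjusted p = 0.102). In monocyte-like clusters alone the medians were -0.46 for glycolysis (adjusted p = 1.53e-05), -0.63 for matrix (adjusted p = 1.56e-04), -0.35 for chemokines and 0.06 for NF-kB (both adjusted p = 0.765).

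Further lists past the threshold in monocyte/macrophage-like cells were MHC class II presentation, dendritic cell maturation, tumour neutrophil and neutrophil granule genes. Of 11 class II genes, H2-Oa, whose product restrains peptide loading, was the 1 that rose (1.58 ± 0.27; 1 adjusted over the list alone; median 0.88, adjusted p = 5.77e-05). The maturation list (5 of 17 higher; 7 higher and 1 lower adjusted over the list alone; median 0.65, adjusted p = 7.89e-05) moved with Cd274, Pdcd1lg2, the IL-15 receptor chain Il15ra (1.60 ± 0.29) and Cd200 (1.56 ± 0.31). The tumour neutrophil list (4 of 12 higher; 6 higher and 1 lower adjusted over the list alone; median 0.88, adjusted p = 5.21e-04) moved with Ptgs2, Cd274, Vegfa and Tnfrsf23 (1.11 ± 0.22). The granule list (2 of 10 higher; 5 adjusted over the list alone; median 0.86, adjusted p = 0.00283) moved with Retnlg (3.66 ± 0.46) and Lcn2 (2.56 ± 0.50), which stayed at 3.70 ± 2.13 and 2.51 ± 1.40 CPM in LNP-Sirpa libraries (SD, n = 2). Neutrophil markers moved with these lists, with summed levels of 214 and 247 CPM in the control and 576 and 468 CPM in the LNP-Sirpa libraries, as did fibroblast markers (296 and 298 against 520 and 548 CPM). With an estimated correlation the adjusted p were 0.358 for the granule list and 0.505 for the other 3. Without control replicate 1 or 2 the class II median was 0.41 and 1.60, without LNP-Sirpa replicate 1 or 2 the maturation median was 0.17 and 1.01, and without LNP-Sirpa replicate 2 the tumour neutrophil median was 0.47. Without control replicate 1, H2-Oa, Cd200 and Tnfrsf23 did not pass (adjusted p = 0.0562, 0.153 and 0.0747), nor did Il15ra, Cd200, Tnfrsf23 and Lcn2 without control replicate 2 (adjusted p from 0.0592 to 0.155). In monocyte-like clusters alone the granule median was -0.31 (adjusted p = 2.04e-04) and the tumour neutrophil median 0.02 (adjusted p = 0.765).

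The other 11 lists did not pass in monocyte/macrophage-like cells (adjusted p from 0.114 to 0.810). They were macrophage checkpoints (median 0.16), engulfment and Fc receptors (0.24), alternative activation (0.38), complement (-0.12), lipid-associated macrophages (0.11), oxidative phosphorylation (-0.11), lysosome (-0.08), cholesterol synthesis (-0.13), dissociation and heat stress (0.10), ribosomal proteins (0.05) and mitochondrially encoded genes (-0.03). The means of the complement and oxidative phosphorylation lists were 0.19 and 0.02, of the other sign than their medians and tests. Single members of these lists did change. The inhibitory receptors Pirb (0.92 ± 0.20) and Cd300lf (1.35 ± 0.26) were higher. Ndufa4 (-1.29 ± 0.26), a subunit of the respiratory chain, was lower (adjusted p of these 3 from 0.0335 to 0.0455), as were Folr2 and Stab1. Arg1, Vegfa and Pdcd1lg2 of the alternative activation list were higher. Adjusted over the list alone, 2 checkpoint genes, 4 engulfment genes and 5 alternative activation genes rose, and 0, 2 and 3 fell. Pirb (adjusted p = 0.425 and 0.129) did not pass without control replicate 1 or 2, nor did Cd300lf without control replicate 1 (adjusted p = 0.125) or LNP-Sirpa replicate 2 (adjusted p = 0.0787). The same held for Ndufa4 without control replicate 1 (-1.09, adjusted p = 0.0709).

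**Figure D2:**
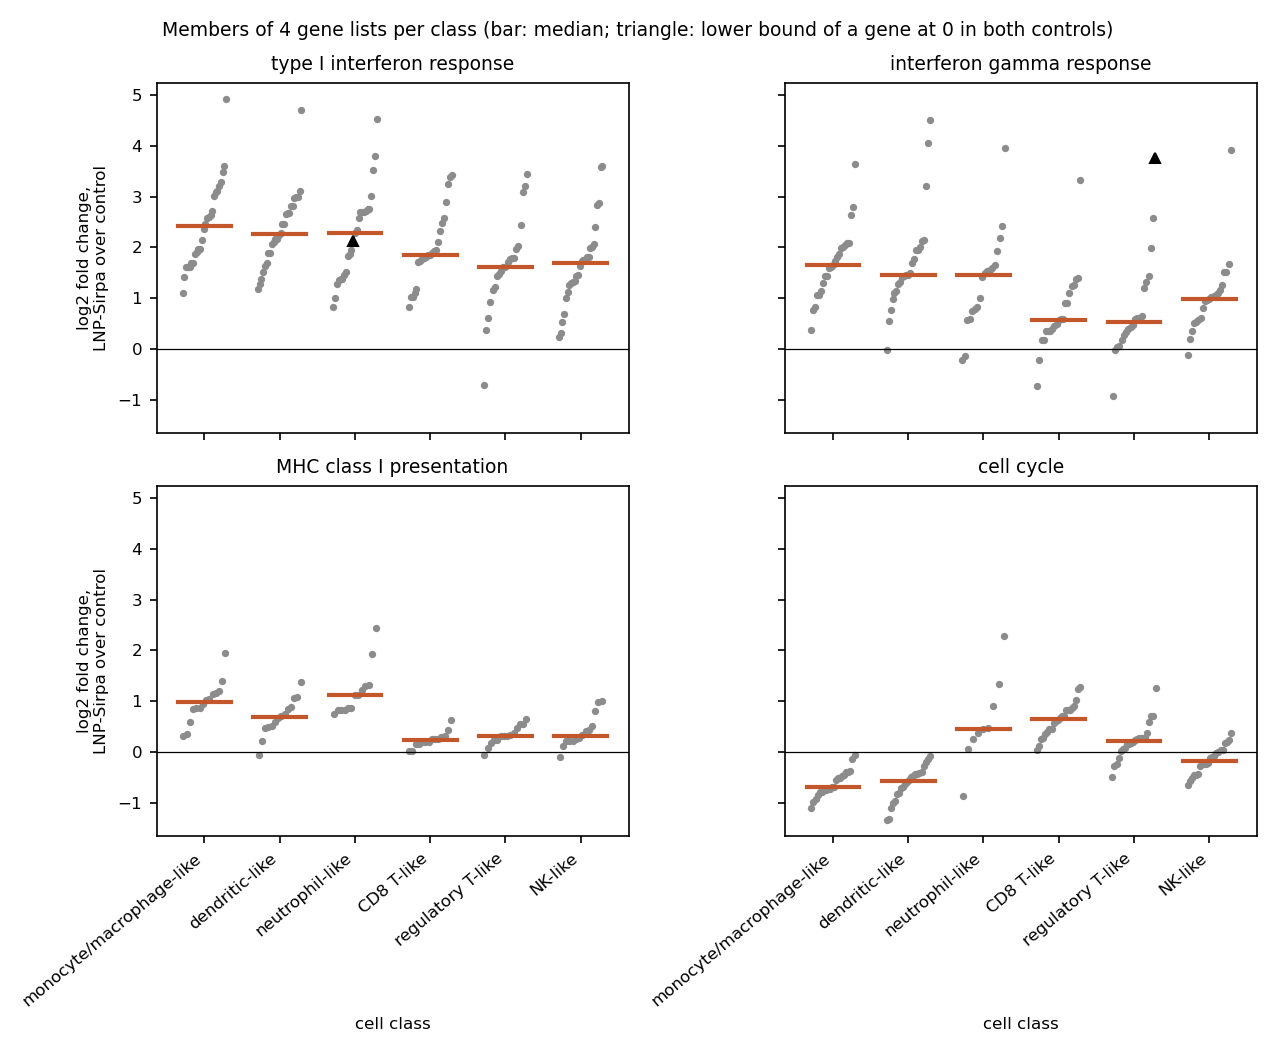
Log2 fold change of LNP-Sirpa over control for each measured member of 4 gene lists in 6 cell classes, with 1 point per gene, a bar at the median and a triangle at the lower bound for genes without a UMI in both control libraries. The type I interferon medians are 2.42 in monocyte/macrophage-like, 2.28 in dendritic-like, 2.28 in neutrophil-like, 1.85 in CD8 T-like, 1.62 in regulatory T-like and 1.69 in NK-like cells.

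Dendritic-like cells held more interferon-induced RNA, including that of chemokines that draw T cells. Cxcl9 rose from 495 ± 273 to 1403 ± 318 CPM and Cxcl10 from 142 ± 18.2 to 384 ± 105 CPM (SD, n = 2; log2 1.504 ± 0.34 and 1.45 ± 0.24, adjusted p = 0.0417 and 0.00560). Nos2 rose by 4.06 ± 0.37 and Arg1 by 1.86 ± 0.26 (adjusted p = 3.84e-05 and 0.00186), and so did the ligand genes of PD-1, Cd274 (1.33 ± 0.21) and Pdcd1lg2 (1.24 ± 0.21). Nos2 stood at 1.6 and 2.6 CPM in the control and 45.0 and 22.4 CPM in the LNP-Sirpa libraries, against 8.8, 16.2, 167 and 117 CPM in phagocytes, while macrophage markers stood at 26.9%, 24.8%, 36.1% and 25.7% of the phagocyte level. Phagocyte RNA was not subtracted here, so it was not excluded as a source of Nos2, Arg1 and other phagocyte genes. Stmn1, which regulates microtubules in dividing cells, fell by 1.33 ± 0.21 and the thymidine kinase Tk1 by 1.35 ± 0.25 (adjusted p = 0.00277 and 0.00778).

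Of 11213 genes tested in dendritic-like cells, 348 changed, 287 higher and 61 lower. The largest rises were Ly6a (3.84 ± 0.30), Ly6c2 (3.83 ± 0.23), Rsad2 (3.00 ± 0.24), Oasl1 (2.99 ± 0.31) and Oasl2 (2.97 ± 0.25). The largest falls were Selenop (-1.84 ± 0.33), Stab1 (-1.71 ± 0.25), the iron carrier Trf (-1.60 ± 0.24), F13a1 (-1.54 ± 0.22) and Tnni2 (-1.51 ± 0.29), and adjusted p over all 10 ran from 2.05e-06 to 0.0172. Of these falls Selenop (113, 141, 48.0 and 15.3 CPM; phagocytes 427, 619, 158 and 97.4), Stab1 (144, 153, 57.4 and 27.5; phagocytes 703, 607, 259 and 148) and F13a1 (136, 119, 50.1 and 34.6; phagocytes 685, 499, 209 and 154) lay near the macrophage marker ratio in the control libraries. The mix of the class also differed, with 97 and 165 control and 129 and 12 LNP-Sirpa cDC1-like cells of 402, 493, 573 and 138 in all, and Tnni2 was among the 10 top markers of the cDC1-like cluster. In the type I interferon list 22 of 26 members rose (26 adjusted over the list alone; median 2.28, adjusted p = 2.48e-91), among them Ifit1 (2.82 ± 0.22) and Isg15 (2.81 ± 0.25). Of the interferon gamma list 17 of 23 rose (21 adjusted over the list alone; median 1.47, adjusted p = 4.36e-45), with Gbp2 (1.95 ± 0.23) and Gbp5 (2.02 ± 0.25). MHC class I had 3 of 14 higher (11 adjusted over the list alone; median 0.70, adjusted p = 9.11e-09), namely H2-T23 (1.37 ± 0.23), H2-Q7 (1.06 ± 0.21) and the immunoproteasome subunit Psmb10 (0.89 ± 0.20). The inflammatory list had 3 of 13 higher (5 adjusted over the list alone; median 0.40, adjusted p = 3.39e-06). These 4 lists gave adjusted p = 0.244 with an estimated correlation. The Ifit, Oasl and Gbp families and H2-Q7 have close copies and are uncertain as single genes. Cell cycle genes fell in 5 of 22 cases (6 adjusted over the list alone; median -0.58, adjusted p = 4.84e-10; adjusted p = 0.459 with an estimated correlation), including Mcm5 (-1 ± 0.24) and Pclaf (-0.96 ± 0.23). Monocyte markers moved with these lists, with summed levels of 437 and 369 CPM in control and 950.0 and 1067 CPM in LNP-Sirpa libraries.

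Smaller shifts in dendritic-like cells concerned maturation (2 of 17 higher; 5 adjusted over the list alone; median 0.44, adjusted p = 0.00286), tumour neutrophil genes (2 of 11; 2 adjusted over the list alone; 0.29, 0.00600) and glycolysis (1 of 21; 3 adjusted over the list alone; 0.26, 0.00442). Past the threshold were also the NF-kB response (1 of 20; 1 adjusted over the list alone; 0.29, 0.0191), myeloid chemokines (3 of 18 higher and 1 lower; 4 and 1 adjusted over the list alone; 0.29, 0.0353) and ribosomal proteins (0 of 93; -0.20, 2.86e-04). Their members past the threshold included Vegfa (1.47 ± 0.35), Tnfaip2 (1.05 ± 0.23), Cxcl3 (1.97 ± 0.49) and the platelet factor Pf4 (-0.83 ± 0.20). With an estimated correlation the adjusted p were 0.459 for maturation, 0.476 for tumour neutrophil, NF-kB and chemokine genes, 0.714 for glycolysis and 0.794 for ribosomal proteins. The other 12 lists did not pass (adjusted p from 0.0753 to 0.747): checkpoints (median -0.20), engulfment (0.13), alternative activation (0.39), complement (-0.06), lipid-associated genes (-0.19), MHC class II (-0.02), oxidative phosphorylation (-0.16), lysosome (-0.18), cholesterol (-0.24), matrix (0.24), dissociation (-0.04) and mitochondrially encoded genes (0.34). For checkpoints, complement, class II and dissociation the means (0.07, 0.33, 0.09 and 0.02) had the other sign. Members of these that changed were the Fc receptor genes Fcgr4 (1.84 ± 0.33) and Fcgr1 (1.11 ± 0.24), Cd300lf (0.92 ± 0.23) and the interleukin 4 receptor gene Il4ra (0.82 ± 0.19). Also among them were Folr2 (-1.35 ± 0.25), Cox5a (1.57 ± 0.30), Ndufa4 (-0.79 ± 0.19) and the protease Mmp12 (0.88 ± 0.20), and adjusted p over all 8 ran from 0.00798 to 0.0452.

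Changed genes in dendritic-like cells numbered 227 with DESeq2 and 179, 257, 582 and 934 without control replicates 1 and 2 and LNP-Sirpa replicates 1 and 2. Of the 40 genes chosen by the rule, 16 did not pass without control replicate 1 (adjusted p from 0.0709 to 0.671; Cd274, Pdcd1lg2, Cxcl9, Cxcl3, Cox5a, Fcgr1, Cd300lf, H2-Q7, Psmb10, Il4ra, Mcm5, Pclaf, Mmp12, Ndufa4, Pf4 and Tnfaip2). Without control replicate 2, 14 did not (0.0504 to 0.578; Vegfa and H2-T23 and all of those named but Cd274, Pdcd1lg2, Cxcl9 and Cox5a). Without LNP-Sirpa replicate 1, 9 were lost (0.0534 to 0.705; Cxcl9, Cxcl3, Cox5a, Fcgr1, Fcgr4, Oasl1, Mcm5, Pclaf and Tk1), Fcgr1 moved to 0.66, Selenop to -2.95 and Tnni2 to -2.32. Leaving out LNP-Sirpa replicate 2 lost 4 (0.0909 to 0.586: Cxcl9, Cox5a, Fcgr4 and Oasl1). Without LNP-Sirpa replicate 1 the chemokine (0.19) and ribosomal (0.03) lists did not pass, and the glycolysis and tumour neutrophil medians were 0.50 and 0.75. Without LNP-Sirpa replicate 2 the NF-kB (0.13), glycolysis (0.11) and tumour neutrophil (0.07) lists did not pass and the ribosomal median was -0.47. Without control replicate 2 the NF-kB (0.30) and chemokine (0.12) lists did not. At the lower cluster resolution the NF-kB (0.01), glycolysis (-0.01) and tumour neutrophil (-0.02) lists were not past the threshold (adjusted p from 0.660 to 0.920) and the chemokine median was -0.41 (adjusted p = 0.0390). In the cDC2-like cluster alone, an alternative added after the data were seen, maturation (0.00, adjusted p = 0.789), NF-kB (-0.09, adjusted p = 0.360), chemokines (0.38, adjusted p = 0.0525) and tumour neutrophil genes (0.26, adjusted p = 0.0987) did not pass. The change of Selenop in dendritic-like cells did not pass there either (-1.67, adjusted p = 0.0543), and that of Tnni2 in dendritic-like cells was -1.29 (adjusted p = 0.0205).

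Neutrophil-like cells of the LNP-Sirpa libraries held more granule and interferon-induced RNA. Ngp, a protein of the granules of young neutrophils, had 0 UMIs in the control libraries and 264 and 97 in the LNP-Sirpa libraries, a rise of at least 17.8-fold. The iron-binding Lcn2 rose from 200 ± 54.8 to 911 ± 194 CPM (SD, n = 2; log2 2.43 ± 0.35, adjusted p = 0.00668), Chil3, a chitinase-like secreted protein, by 5.73 ± 0.94 and the chemokine Ccl5 by 3.00 ± 0.46 (adjusted p = 0.0108 and 0.00708). Isg15 rose from 780 ± 154 to 4017 ± 1785 CPM (log2 2.57 ± 0.36, adjusted p = 0.00668) and Zbp1 by 2.69 ± 0.40. The class was small (29 and 51 control, 299 and 182 LNP-Sirpa cells), and Chil3 UMIs in control came from replicate 1 alone.

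In neutrophil-like cells 64 of 4869 genes changed, 51 higher and 13 lower. Ms4a4c (at least 10.0-fold), Ly6c2 (5.75 ± 0.48), Ifit2 (4.53 ± 0.69), Ifit1 (3.81 ± 0.59), Nos2 (3.96 ± 0.79), Gbp2 (2.42 ± 0.44) and Cd274 (1.92 ± 0.39) rose. Fcrls (-3.02 ± 0.42), Cbr2 (-2.86 ± 0.38), Pmp22 (-2.51 ± 0.37), Igfbp4 (-2.42 ± 0.52), Folr2 (-2.09 ± 0.44) and Stab1 (-1.997 ± 0.41) fell, and adjusted p of the rises and falls ran from 2.47e-04 to 0.0460. Macrophage markers summed to 14400 and 19850 CPM in the control and 11140 and 9624 CPM in the LNP-Sirpa libraries, 65.6%, 71.7%, 55.1% and 50.5% of their level in phagocytes, while monocyte markers stood at 1625, 921, 3916 and 3266 CPM. Type I interferon genes were higher for 11 of 25 members (24 adjusted over the list alone; median 2.34, or 2.28 with Ifi205, absent from the controls, at its bound of at least 4.4-fold; adjusted p = 1.91e-32; adjusted p = 0.465 with an estimated correlation). Granule genes (2 of 8 higher; 5 higher and 1 lower adjusted over the list alone; median 1.42, 3.14e-06) and MHC class I (0 of 13; 7 adjusted over the list alone; 1.11, 8.24e-08) passed, as did inflammatory genes (2 of 11; 2 adjusted over the list alone; 0.37, 9.27e-04) and chemokines (1 of 16; 1 higher and 1 lower adjusted over the list alone; 0.65, 0.00415). All 4 gave adjusted p = 0.443 with an estimated correlation. Also past the threshold were interferon gamma (3 of 18; 6 adjusted over the list alone; 1.46; 2.70e-08), NF-kB (0 of 20; 1 adjusted over the list alone; 0.47; 0.00415), MHC class II (0 of 8; 0.59; 0.0276) and glycolysis genes (0 of 21; 0.30, 0.0276). These had adjusted p = 0.579, 0.586, 0.753 and 0.922 with an estimated correlation.

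The other 15 lists did not pass in neutrophil-like cells (adjusted p from 0.0554 to 0.953). Their medians were those of checkpoints (0.29), engulfment (0.31, mean -0.13), alternative activation (0.22), complement (-0.32), lipid-associated genes (0.09), oxidative phosphorylation (-0.05, mean 0.07), lysosome (-0.37) and cholesterol (0.05, mean -0.09). The others were matrix (0.16), cell cycle (0.45), tumour neutrophil (0.23), maturation (0.19), dissociation (-0.23), ribosomal (0.01) and mitochondrially encoded genes (0.13). Changed genes numbered 177, 143, 88 and 140 without control replicates 1 and 2 and LNP-Sirpa replicates 1 and 2. Without control replicate 1, Chil3 and Nos2 had no control UMI and so no fold. MHC class II (0.41) and glycolysis (-0.01) did not pass there, and the interferon gamma and inflammatory medians were 0.96 and 0.74. Without control replicate 2, Nos2 did not pass (2.55, adjusted p = 0.0933), Ccl5 was 4.61, and the medians were 0.92 (class II), 0.93 (glycolysis) and 1.39 (inflammatory). Without LNP-Sirpa replicate 1, class II did not pass (0.44, adjusted p = 0.212), and the interferon gamma and glycolysis medians were 0.93 and 0.59. Without LNP-Sirpa replicate 2, NF-kB (0.24, adjusted p = 0.374) and glycolysis (-0.00, adjusted p = 0.939) did not pass and the chemokine median was 0.34. After subtraction of an assumed phagocyte profile at 25%, 50%, 75% and 100% of its estimate, an alternative added after the data were seen, 27, 1, 0 and 0 genes were called. At full strength the 48 of the 64 genes still tested kept their direction, with a median size of 2.66 before and 3.08 after. The median SE went from 0.46 to 0.85 and 16 genes were set to 0 UMIs. The type I interferon list still passed (median 2.34), and interferon gamma did not (0.83, adjusted p = 0.605).

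CD8 T-like cells of the LNP-Sirpa libraries held more RNA of a cytotoxic granule enzyme and of interferon-induced genes. Gzmb, encoding granzyme B, rose from 350.1 ± 59.9 to 1213 ± 219 CPM (SD, n = 2; log2 1.82 ± 0.23, adjusted p = 8.55e-04), and Il10, an anti-inflammatory cytokine gene, by 2.24 ± 0.45 (adjusted p = 0.0419). Isg15 rose by 2.12 ± 0.27, Zbp1 by 1.85 ± 0.28, Ifitm3 by 1.76 ± 0.20 and Ly6a by 2.18 ± 0.23, and Pclaf, which acts in DNA replication, by 1.23 ± 0.20 (adjusted p from 2.67e-04 to 0.0112). Gzme, encoding another granzyme, fell by 1.18 ± 0.24 and the opioid precursor gene Penk by 1.85 ± 0.29 (adjusted p = 0.0491 and 0.0120). Granzyme genes have close copies and are uncertain as single members.

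In CD8 T-like cells 45 of 9972 genes changed, 26 higher and 19 lower. Stab1 (-2.26 ± 0.23), F13a1 (-2.10 ± 0.26), Selenop (-2.10 ± 0.25), Lyz2 (-1.34 ± 0.22) and Lrp1 (-1.18 ± 0.25) also fell. Nos2 (3.33 ± 0.56) and the interferon gamma-induced Igtp (1.38 ± 0.24) rose (adjusted p of these 7 from 2.67e-04 to 0.0491). Macrophage markers summed to 3870 and 3932 CPM in the control and 2516 and 1947 CPM in the LNP-Sirpa libraries, and NK markers to 1344, 928, 1558 and 4380 CPM. In the type I interferon list were 2 of 23 members higher (20 adjusted over the list alone; median 1.85, adjusted p = 7.79e-38) and in the cell cycle list 1 of 22 (8 adjusted over the list alone; 0.66, 1.74e-11). Interferon gamma had 2 of 21 (4 higher and 1 lower adjusted over the list alone; 0.58, 6.16e-09), cholesterol synthesis 0 of 17 (0.45, 4.85e-04) and MHC class I 0 of 14 (0.23, 0.0355). All 5 stood at adjusted p = 0.776 with an estimated correlation. Cytotoxicity (1 of 20 higher and 1 lower; 2 and 2 adjusted over the list alone; median 0.23, adjusted p = 0.304) and exhaustion (0 of 18; -0.19, 0.349) did not pass, nor did 12 further lists (adjusted p from 0.191 to 0.770). Medians were those of checkpoints (-0.40), MHC class II (-0.12), NF-kB (0.00), glycolysis (0.11), oxidative phosphorylation (0.01) and naive and memory genes (0.22). The remaining lists were activation (0.00, mean -0.09), regulatory effector genes (0.17), NK receptors (0.10), dissociation (-0.01), ribosomal (-0.10) and mitochondrially encoded genes (0.04).

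Changed genes in CD8 T-like cells numbered 29 with DESeq2 and 94 without cluster 39, of which 128 of 132 cells came from LNP-Sirpa replicate 2 (an alternative added after the data were seen). There were 12, 33, 303 and 298 without control replicates 1 and 2 and LNP-Sirpa replicates 1 and 2. Of the 16 genes chosen by the rule, 8 did not pass without control replicate 1 (Gzme, Igtp, Il10, Isg15, Lrp1, Lyz2, Pclaf and Penk, adjusted p from 0.0630 to 0.424) and 6 without control replicate 2 (Igtp, Il10, Lyz2, Nos2, Pclaf and Zbp1, adjusted p from 0.0816 to 0.317). Without LNP-Sirpa replicate 1, MHC class I did not pass (0.16, adjusted p = 0.0691), and the type I interferon, cell cycle and interferon gamma medians were 1.14, 0.43 and 0.38. Cholesterol synthesis did not pass without LNP-Sirpa replicate 2 (0.04, adjusted p = 0.281). Without control replicate 2, MHC class I did not (0.19, adjusted p = 0.386), and the cholesterol and interferon gamma medians were 0.71 and 0.99. Subtraction of the phagocyte profile at 25%, 50%, 75% and 100% left 20, 12, 3 and 2 of the 45 genes past the threshold (20, 13, 4 and 4 called in all). At full strength 40 of the 45 were still tested, with a median size of 1.41 before and 1.56 after and a median SE of 0.25 before and 0.32 after, and 12 were set to 0. The type I interferon list still passed (median 1.76), and interferon gamma did not (0.23, adjusted p = 0.234).

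Regulatory T-like cells also held more Gzmb, which rose from 339 ± 23.5 to 666 ± 205 CPM (SD, n = 2; log2 0.99 ± 0.23, adjusted p = 0.0272), and more Cst7, which regulates proteases of cytotoxic granules (0.88 ± 0.22, adjusted p = 0.0356). Interferon-induced Ifi27l2a rose from 1068 ± 241 to 3287 ± 1205 CPM (log2 1.61 ± 0.24, adjusted p = 1.24e-04), Rsad2 by 1.79 ± 0.34, Bst2, which tethers viruses, by 1.17 ± 0.25 and Ifi204 by 1.71 ± 0.39 (adjusted p from 0.0138 to 0.0382). AA467197, which encodes a paralog of the NDUFA4 subunit, rose by 2.12 ± 0.24 (adjusted p = 3.51e-07), and Nos2, at 0 UMIs in the controls and 61 and 47 in LNP-Sirpa libraries, by at least 13.6-fold. Both were also among the rises in phagocytes, where AA467197 went from 217 to 1222 CPM (53.9 to 234 CPM in regulatory T-like cells) and Nos2 from 12.5 to 142 CPM (0 to 31.1 CPM). With the phagocyte profile subtracted at 50% and 75%, AA467197 in regulatory T-like cells stood at 1.56 (adjusted p = 0.0308) and -0.56 (adjusted p = 0.907), Rsad2 at 1.05 and -0.20, and Nos2 was too low to be tested. Dscam, an adhesion molecule, fell by 2.41 ± 0.29 and the cold-inducible RNA-binding Cirbp by 1.02 ± 0.23 (adjusted p = 1.07e-06 and 0.0145).

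In regulatory T-like cells 57 of 8591 genes changed, 47 higher and 10 lower. Ly6c2 (2.71 ± 0.27), Ms4a4b (1.72 ± 0.24), Gbp4 (1.21 ± 0.27), Gbp2 (1.33 ± 0.30) and Cox5a (1.42 ± 0.26) also rose, and the macrophage genes Selenop (-1.56 ± 0.23), F13a1 (-1.51 ± 0.26) and Stab1 (-1.26 ± 0.25) fell (adjusted p from 7.42e-09 to 0.0382). Macrophage markers summed to 5991 and 5192 CPM in the control and 4396 and 5031 CPM in the LNP-Sirpa libraries, and CD8 T markers to 35.8, 85.9, 223 and 165 CPM. Among type I interferon genes 4 of 21 were higher (11 adjusted over the list alone; median 1.62, adjusted p = 8.27e-33), and of interferon gamma genes 3 of 20 (8 adjusted over the list alone; 0.53, also with Nos2 at its bound, 3.67e-11). Cytotoxicity had 2 of 18 higher (5 adjusted over the list alone; 0.61, 6.78e-05) and MHC class I 0 of 14 (0.32, 0.00135). Each stood at adjusted p = 0.427 with an estimated correlation. Ribosomal protein genes were lower as a list (0 of 90; median -0.15, adjusted p = 8.18e-05; adjusted p = 0.872 with an estimated correlation). Not past the threshold were 14 lists (adjusted p from 0.0784 to 0.925). Medians were those of regulatory effector genes (0.06, 1 of 20 higher), checkpoints (-0.02, mean 0.12), MHC class II (0.31), NF-kB (0.11), glycolysis (-0.06), oxidative phosphorylation (-0.11), cholesterol (0.12) and cell cycle (0.22). The remaining lists were exhaustion (-0.06, mean 0.02), naive and memory (0.16), activation (0.07), NK receptors (0.24), dissociation (0.03, mean -0.01) and mitochondrially encoded genes (0.01, mean -0.04).

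Changed genes in regulatory T-like cells numbered 17 with DESeq2 and 69, 150, 96 and 252 without control replicates 1 and 2 and LNP-Sirpa replicates 1 and 2. Of the 18 genes chosen by the rule, 6 did not pass without control replicate 1 (Cox5a, Cst7, Gbp2, Gzmb, Ifi27l2a and Stab1, adjusted p from 0.0808 to 0.341). Another 6 did not without control replicate 2 (Bst2, Cirbp, Cst7, Gbp4, Gzmb and Ifi204, 0.0523 to 0.286), and Gbp2 moved to 0.88 and 2.06 in these fits. Without LNP-Sirpa replicate 1, 6 did not pass (0.0715 to 0.526), Bst2 (0.65), Ifi204 (1.00 at 0.526), Rsad2 (1.13), Cirbp (-0.87), Gbp2 (1.01) and Gbp4 (0.96). In the same fit MHC class I (0.18) and ribosomal proteins (-0.01) did not pass. The type I interferon and interferon gamma medians were 0.78 and 0.27. Without LNP-Sirpa replicate 2, Cst7 (0.67) and Gzmb (0.57) did not pass and the ribosomal median was -0.35. The ribosomal list did not pass at the lower cluster resolution (-0.08, adjusted p = 0.0969). Subtraction at 25%, 50%, 75% and 100% left 34, 13, 9 and 9 of the 57 genes past the threshold (35, 15, 12 and 15 called in all). At full strength 40 of the 57 were still tested, 35 in the same direction, with a median size of 1.36 before and 1.47 after and a median SE of 0.27 before and 0.36 after, and 22 were set to 0. The type I interferon list still passed (1.28), and interferon gamma did not (0.26, adjusted p = 0.0901).

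In NK-like cells Gzma, encoding granzyme A, rose from 1078 ± 210.4 to 5131 ± 1852 CPM (SD, n = 2; log2 2.29 ± 0.34, adjusted p = 0.00637), Gzmb by 1.20 ± 0.25 and the chemokine gene Ccl5 by 2.17 ± 0.37 (adjusted p = 0.0378 and 0.0256). Gzmb did not pass without control replicate 1 or 2 (adjusted p = 0.0840 and 0.573). Pdcd1, the gene of the inhibitory receptor PD-1, rose by 1.40 ± 0.29 (adjusted p = 0.0366). The interferon-induced Irf7 rose by 2.02 ± 0.33, Oasl1 by 1.99 ± 0.35, Zbp1 by 1.76 ± 0.26, Usp18 by 1.81 ± 0.30 and Rtp4 by 1.82 ± 0.34 (adjusted p from 0.00672 to 0.0449). Ccl1, a chemokine gene of activated lymphocytes, fell from 174 ± 48.6 to 13.3 ± 10.4 CPM (log2 -3.42 ± 0.35, adjusted p = 0.00287).

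In NK-like cells 108 of 11054 genes changed, 77 higher and 31 lower. Ly6a (3.07 ± 0.26) and Nos2 (3.92 ± 0.36) also rose, and F13a1 (-1.91 ± 0.22), Cd93 (-1.54 ± 0.28), Stab1 (-1.53 ± 0.28), Lyz2 (-1.40 ± 0.30) and Lrp1 (-0.98 ± 0.20) fell (adjusted p from 8.12e-05 to 0.0441). Phagocyte RNA was not excluded for Nos2 (33.2 and 26.2 CPM in LNP-Sirpa libraries) or these falls. Macrophage markers summed to 6544 and 13120 CPM in the control and 7365 and 4991 CPM in the LNP-Sirpa libraries, and NK markers to 4546, 3219, 6926 and 9211 CPM. The type I interferon list had 6 of 26 members higher (10 adjusted over the list alone; median 1.69, adjusted p = 1.65e-24) and interferon gamma 1 of 21 (10 adjusted over the list alone; 0.98, 6.10e-16). MHC class I had 0 of 14 (3 adjusted over the list alone; 0.31; 6.48e-04), activation 0 of 12 (0.35; 0.0119) and exhaustion 1 of 18 (1 adjusted over the list alone; 0.18, 0.0302). Each stood at adjusted p = 0.499 with an estimated correlation. Cytotoxicity had 3 of 20 higher (4 higher and 2 lower adjusted over the list alone; median 0.11, adjusted p = 0.0386; adjusted p = 0.921 with an estimated correlation). The other 13 lists did not pass (adjusted p from 0.225 to 0.764). Medians were those of NK receptors (0.17), checkpoints (-0.17), MHC class II (-0.12), NF-kB (0.20), glycolysis (0.03), oxidative phosphorylation (-0.13), cholesterol (-0.10), cell cycle (-0.17), naive and memory (0.13, mean -0.01), regulatory effector genes (0.22), dissociation (-0.11), ribosomal (-0.01) and mitochondrially encoded genes (-0.09).

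Changed genes in NK-like cells numbered 64 with DESeq2 and 203, 168, 44 and 240 without control replicates 1 and 2 and LNP-Sirpa replicates 1 and 2. Of the 17 genes chosen by the rule, 8 did not pass without LNP-Sirpa replicate 1 (adjusted p from 0.0572 to 0.512): Irf7 (1.17), Oasl1 (1.17), Rtp4 (0.88), Usp18 (1.04), Zbp1 (1.18), Pdcd1 (1.67), Lyz2 (-1.36) and Lrp1 (-0.97), and Cd93 moved to -2.46. In that fit the type I interferon median was 0.31, interferon gamma 0.48, activation 0.20 and cytotoxicity 0.36, and exhaustion did not pass (0.27, adjusted p = 0.0849). Without LNP-Sirpa replicate 2, Lyz2, exhaustion (0.22), cytotoxicity (-0.06) and activation (0.29) did not pass. Without control replicate 1, Gzmb, Pdcd1 and exhaustion (0.17) did not, and the cytotoxicity median was 0.28. Without control replicate 2, Gzmb, Lrp1, Lyz2 (-0.92), cytotoxicity (-0.03) and activation (0.26) did not. Cytotoxicity, exhaustion and activation were also lost with the stricter cell filter (-0.06, 0.19 and 0.17) and at the higher resolution (-0.08, 0.20 and 0.18). Subtraction at 25%, 50%, 75% and 100% left 65, 55, 18 and 4 of the 108 genes past the threshold (66, 68, 42 and 17 called in all). At full strength 77 of the 108 were still tested, with a median size of 1.53 before and 1.34 after and a median SE of 0.28 before and 0.36 after, and 36 were set to 0. Neither the type I interferon (0.20) nor the interferon gamma (0.41) list passed then (both adjusted p = 0.425).

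**Figure D3:**
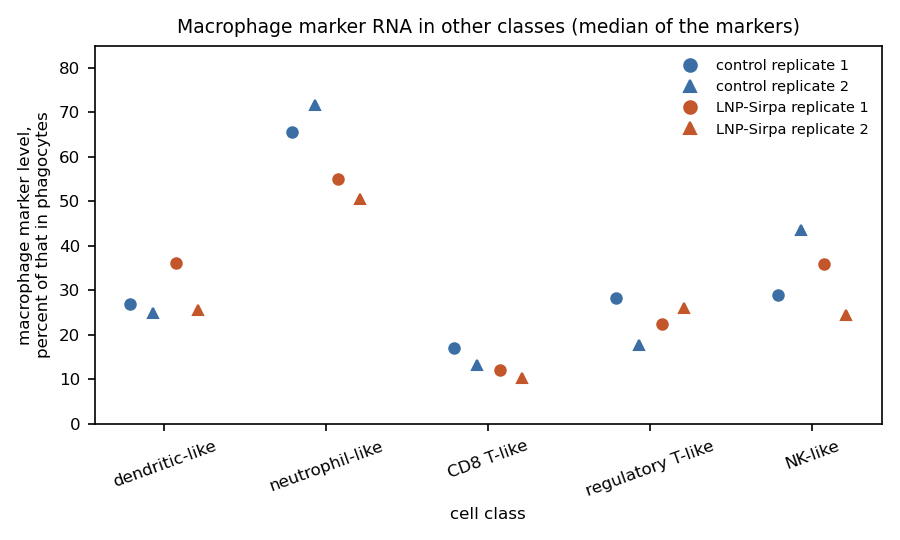
Level of macrophage markers in 5 classes as a percent of their level in monocyte/macrophage-like cells of the same library, with 1 point per library and colour for the group. Neutrophil-like cells lie at 65.6%, 71.7%, 55.1% and 50.5% and CD8 T-like cells at 17.0%, 13.3%, 12.2% and 10.3% in control replicates 1 and 2 and LNP-Sirpa replicates 1 and 2.

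Neutrophil-like cells were 0.448 ± 0.0601% of kept cells in control and 2.57 ± 0.636% in LNP-Sirpa libraries (SD, n = 2; 5.73-fold, adjusted p = 0.0548), at 0.405%, 0.490%, 3.02% and 2.12% in the single libraries. Regulatory T-like cells stood at 1.54 ± 0.186% and 3.89 ± 0.702% (2.52-fold, adjusted p = 0.191), CD8 T-like cells at 2.04 ± 1.64% and 4.44 ± 0.041% (2.17-fold, adjusted p = 0.409) and B-like cells at 0.882 ± 0.0438% and 0.245 ± 0.0820% (0.279-fold, adjusted p = 0.132). CD8 T-like cells were 0.879% and 3.20% of the single control libraries. Their log2 share differed by 0.47 and 2.33 without control replicate 1 or 2. Of the 383 such cells in LNP-Sirpa replicate 2, 255 lay outside the cluster that came from that library. No class of 14 passed with edgeR, 4 had an unadjusted p under 0.05, and the smallest exact permutation p was 0.3333, the lowest that 2 libraries per group allow. Unassigned T-like cells differed by 3.36-fold (adjusted p = 0.156), CD4 T-like cells by 2.01-fold (adjusted p = 0.409), cDC1-like by 0.493-fold (adjusted p = 0.563) and NK-like by 1.07-fold (adjusted p = 0.910). Monocyte-like clusters were 2.73 ± 0.8% and 16.8 ± 5.78% of kept cells (6.17-fold, adjusted p = 0.0548), the largest fold at resolution 2 without doublets. Single libraries held 3.29%, 2.16%, 12.7% and 20.9%. Macrophage-like clusters made up 67.3%, 61.1%, 34.9% and 40.4% (0.586-fold, adjusted p = 0.409). The log2 monocyte-like share differed by 2.94 and 2.23 without LNP-Sirpa replicate 1 or 2. At the lower resolution monocyte-like cells numbered 306, 256, 666 and 1606 (236, 225, 1261 and 1794 at resolution 2). The share passed with the stricter cell filter (2.95, adjusted p = 0.0427) and at the higher resolution (3.27, adjusted p = 0.0258). It also passed with TMM scaling (3.02, adjusted p = 0.0381) and with named immune cells as the denominator (2.71, adjusted p = 0.0449). The neutrophil-like log2 fold was 2.24 and 2.75 without LNP-Sirpa replicate 1 or 2. The neutrophil-like share passed with the stricter cell filter (adjusted p = 0.0427). It also passed at the higher resolution (adjusted p = 0.0439), with TMM scaling over the classes (adjusted p = 0.0261) and with named immune cells as the denominator (adjusted p = 0.0449). Without LNP-Sirpa replicate 1 the cDC1-like, B-like and NK-like values were -3.38, -2.23 and -1.38. CD8 T-like cells per regulatory T-like cell numbered 0.525 and 2.27 in control and 1.01 and 1.32 in LNP-Sirpa libraries (log2 difference 0.08, exact permutation p = 1). This difference was -0.98 and 1.13 without control replicate 1 or 2 and 0.27 and -0.12 without LNP-Sirpa replicate 1 or 2.

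**Figure D4:**
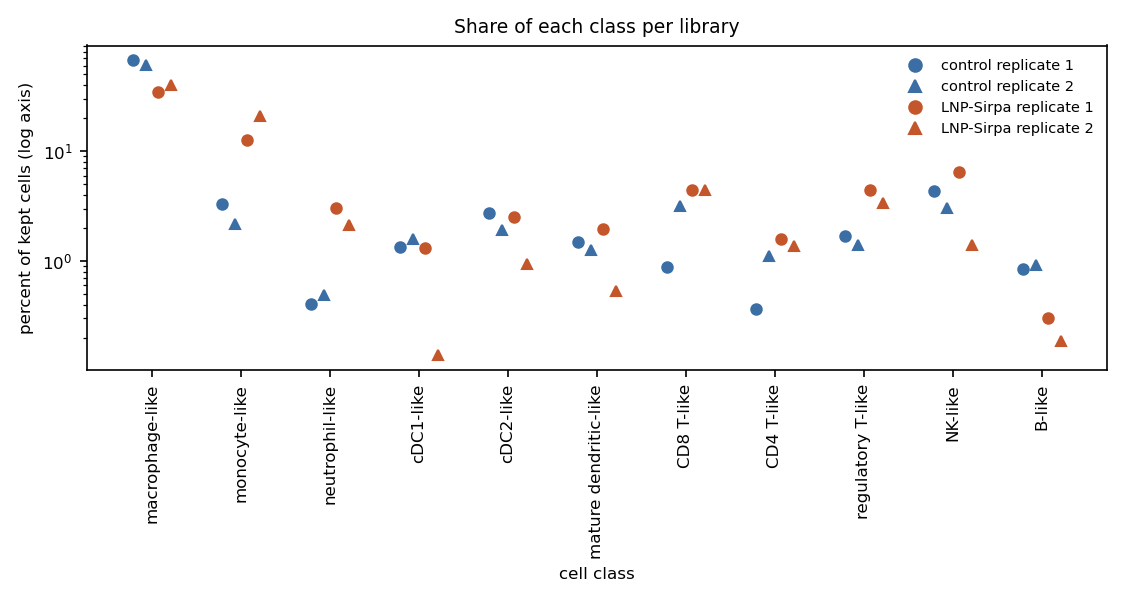
Share of kept cells in percent on a log axis for 11 classes, with 1 point per library, colour for the group and marker shape for the replicate. Neutrophil-like cells lie at 0.405% and 0.490% in control and at 3.02% and 2.12% in LNP-Sirpa libraries.

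Changes in phagocytes and in the T/NK-like sum differed. MHC class II genes had a median of 0.88 in phagocytes and -0.01 in T/NK-like cells (difference -0.92, adjusted p = 9.12e-16), type I interferon genes 2.42 and 1.86 (-0.55, adjusted p = 3.13e-08) and cell cycle genes -0.69 and 0.18 (0.89, adjusted p = 1.30e-30). A test of the interaction of treatment and class found 400 of 15647 genes, 104 with a more positive and 296 with a less positive change in T/NK-like cells, and 10 of 13 lists, none of which passed with an estimated correlation (adjusted p from 0.162). All T/NK-like cells as 1 sum had 19 changed genes. NK-like cells were 310 of its 589, 317 of 997, 642 of 2080 and 121 of 1074, so shifts in mix were not separated from response. The more positive and less positive counts were 212 and 720 with doublets kept and 59 and 161 with the stricter cell filter. Both cell groups came from the same 4 samples.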

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

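The results below were singled out because the change after treatment differed between phagocytes and T/NK-like cells by an interaction test with edgeR and camera. All tests of explanations in this part were chosen after the result was seen. The differences, T/NK-like minus phagocyte, were -0.53 for macrophage checkpoints, -0.92 for MHC class II, -0.60 for MHC class I, -0.55 for type I interferon, -0.44 for interferon gamma, -0.35 for NF-kB, -0.47 for glycolysis, -0.24 for ribosomal proteins, 0.25 for cholesterol synthesis and 0.89 for cell cycle genes. None passed with an estimated correlation, where the lowest adjusted p was 0.162. Phagocyte RNA in T/NK-like cells was not subtracted for these differences.

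The first pattern weighed was the interferon rise and the lower genes in lymphocytes, which RNA carried over from phagocytes could produce if type I interferon genes rose relative to phagocytes at the ratio of macrophage markers, 11.4% in CD8 T-like, 24.4% in regulatory T-like and 31.3% in NK-like cells. The rise stood at 2.65 (quartiles 1.06 and 4.1), 1.74 (1.03 and 3.37) and 0.93 times (0.67 and 1.35) that ratio, and full subtraction of the phagocyte profile left a median of 67% (quartiles 15.3% and 77.8%), 55.2% (14.3% and 70.9%) and 0% (-12.6% and 24.8%) of it. The list stayed past the threshold in CD8 T-like and regulatory T-like cells (medians 1.85 and 1.76, 1.62 and 1.28, after subtraction over the 16 of 23 and 17 of 21 members still tested; before subtraction adjusted p = 0.776 and 0.427 with an estimated correlation), which by bounds set after these values were seen, and if carried RNA had the phagocyte profile, argues against carried RNA as the source of the whole rise there, where 15 of 23 and 10 of 20 members kept over 50%, and leaves it possible for the other members and as the source in NK-like cells (1.69 and 0.20). Of the genes lower in CD8 T-like and NK-like cells, 84.2% and 77.4% stood within a factor of 2 of the marker ratio in the controls, as carried RNA would give, and of those in regulatory T-like cells 50%, which decides nothing. Above the ratio were 3 genes in CD8 T-like, 5 in regulatory T-like and 7 in NK-like cells.

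The second pattern was the change within phagocytes, which a shift of cells between clusters could produce. Macrophage-like clusters alone were no test of it, since they split by group themselves (2186 control and 76 LNP-Sirpa cells in the largest), so the change was read inside the 16 clusters with at least 20 cells of every library. Type I interferon genes rose in 16 of 16 (medians 0.36 to 2.48, lower quartile 47.7% of the class value), which by bounds set after these values were seen argues against such a shift as the source of the whole rise, and leaves it possible for part of it. Lower genes, picked between 1 control and 1 LNP-Sirpa library and read between the other 2, fell in 14, 12, 15 and 15 of 16 clusters (lowest lower quartile 12.4%), and glycolysis, chemokine and matrix genes rose in 10, 14 and 11 of 16 (lowest lower quartile -6.3%), so for these a shift and a change inside cells cannot be told apart, because clusters were formed from the same expression values. Shifts finer than the clusters, RNA carried between cells of a library and a difference between tumours were not tested and stay possible beside an effect of the treatment.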

How the results depend on the processing

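Each result was recomputed with 1 choice changed at a time; the cause was not tested unless stated. Counted over results and settings, 3170 kept direction and side of the threshold, 683 were weaker, 35 stronger, 86 moved (counts that differed over 1.5-fold) and 43 reversed. No list passed with an estimated correlation or with fry: 0 in monocyte/macrophage-like, dendritic-like, neutrophil-like, CD8 T-like, regulatory T-like and NK-like cells.

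Changed genes in monocyte/macrophage-like cells numbered 1398 with DESeq2, 1384 without a filter on low counts, 1340 with the replicate block, 230 in macrophage-like and 246 in monocyte-like clusters alone, and 465 to 2032 with a library left out. In dendritic-like cells they were 227 with DESeq2, 618 without a filter and 179 to 934 with a library left out, and 7 lists passed in the cDC2-like cluster alone. In neutrophil-like cells they were 194 without a filter (14 lists; the median of all genes was then 0.49), 39 at resolution 3, 140 to 177 with a library left out (88 without LNP-Sirpa replicate 1), and 27, 1, 0 and 0 after subtraction at 25%, 50%, 75% and 100% (4 lists at 50%). In CD8 T-like cells they were 29 with DESeq2, 246 without a filter, 19 with doublets kept, 73 at resolution 3, 94 without the 1-library cluster, 12 to 303 with a library left out (up to 10 lists), and 20, 13, 4 and 4 after subtraction. In regulatory T-like cells they were 17 with DESeq2, 173 without a filter, 162 with the replicate block, 89 with the stricter filter, 94 at resolution 1, 96 to 252 with a library left out (69 without control replicate 1; 6 to 8 lists), and 35, 15, 12 and 15 after subtraction (8 lists at 75%). In NK-like cells they were 64 with DESeq2, 364 without a filter, 173 with doublets kept (10 lists), 56 with the stricter filter, 44 to 240 with a library left out, and 66, 68, 42 and 17 after subtraction, where 0 lists passed at full strength. Sirpa in these lymphocyte classes was too low to be tested at full strength.

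Shares past the threshold numbered 2 with the stricter filter, 2 at resolution 3, 3 with TMM, 2 with named immune cells as denominator and 4 to 5 with an LNP-Sirpa library left out. The log2 ratio of CD8 T-like to regulatory T-like cells was -0.08 at resolution 1 and -0.98 to 1.13 with a library left out.

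In monocyte-like clusters alone, directions reversed for Sirpa (0.067), chemokines (-0.35), glycolysis (-0.46), matrix (-0.63), cell cycle (0.22) and granule lists (-0.31), and for Sod2 (-0.023), Cxcl3 (-0.35), Ero1a (-0.22), Mmp19 (-0.13), Adam8 (-0.30), Mki67 (0.043), Cenpf (0.026) and Nusap1 (0.26). In dendritic-like cells, ribosomal proteins reversed with a library left out (-0.467 to 0.033), chemokines with doublets kept (-0.02) and at resolution 1 (-0.41), glycolysis (-0.005) and tumour neutrophil genes (-0.023) at resolution 1 and NF-kB in the cDC2-like cluster (-0.088). In neutrophil-like cells glycolysis reversed with a library left out (-0.011 to 0.931), MHC class II with doublets kept (-0.24) and Sirpa after subtraction (0.40). In regulatory T-like cells Rsad2 (-7.29), Stab1 (1.97) and Gbp2 (-0.84) reversed after full subtraction and AA467197 (-0.56) and Rsad2 (-0.20) at 75%. In NK-like cells cytotoxicity reversed with a library left out (-0.055 to 0.359), with the stricter filter (-0.064), at resolution 3 (-0.077) and after subtraction at 75% (-0.011) and 100% (-0.085), as did MHC class I (-0.006) and Oasl1 (-1.87) after full subtraction. Shares reversed for NK-like cells with the replicate block (-0.26) and with a library left out (-1.384 to 0.817), monocyte/macrophage-like cells with doublets kept (0.19), and with a library left out mature dendritic-like cells (-1.35 to 0.51) and the share of cDC2-like cells (-1.319 without LNP-Sirpa replicate 1 to 0.123 without LNP-Sirpa replicate 2).

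Deviations of equal replicate numbers from their group means correlated at -0.013, -0.092, 0.023, 0.015, 0.044 and -0.059 in the classes in the order above, and the replicate block weakened 12 named genes and 1 list and strengthened 1 gene. Simulated changes of log2 1 were recovered least often in neutrophil-like cells (9.8% of genes), the class with the smallest sums (from 92283 UMIs) and the highest common dispersion (0.0522), and these were not separated.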

Other observations

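Fibroblast-like cells, which no planned comparison covered, also held more interferon-induced RNA after LNP-Sirpa treatment. Ubd, a ubiquitin-like modifier, rose by 3.33 ± 0.30, Bst2 by 2.87 ± 0.33 and Zbp1 by 2.45 ± 0.24 (log2 ± SE, n = 2 libraries per group, edgeR, adjusted p from 0.00158 to 0.00286), while the macrophage genes Selenop and Stab1 fell by 2.70 ± 0.29 and 2.42 ± 0.27. Fibroblasts were not expected among CD45+ cells. Macrophage markers stood at 8.86%, 8.29%, 4.68% and 6.43% of the phagocyte level in this class, and Selenop and Stab1 at 77.4 and 93.7 CPM in control replicate 1 (427 and 703 CPM in phagocytes). Phagocyte RNA was not subtracted and not excluded as a source. Of 10379 genes 129 changed, 110 higher and 19 lower. Type I interferon genes rose in 16 of 26 cases (median 2.65, adjusted p = 1.34e-82; adjusted p = 0.313 with an estimated correlation), interferon gamma genes in 13 of 22 (1.97, 4.10e-60; 0.313 with an estimated correlation) and MHC class I genes in 7 of 14 (1.17, 1.18e-22; 0.341). Also past the threshold were MHC class II (1 of 9; 1.02, adjusted p = 1.24e-07; 0.373 with an estimated correlation), ribosomal (0 of 92; 0.20, 0.00125; 0.882), mitochondrially encoded (0 of 11; 0.33, 0.0393; 0.856) and, lower, cell cycle genes (0 of 22; -0.23, 0.00856; 0.635). This comparison was chosen after the data were seen, and its genes were picked after their values were seen.

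Ndufa4, a subunit gene of the respiratory chain, and AA467197, which encodes a paralog of it, moved in opposite directions in monocyte/macrophage-like cells (-1.29 ± 0.26 and 2.68 ± 0.26). The hypothesis that cells with AA467197 RNA hold less Ndufa4 RNA was written before its test. At equal depth the ratio of Ndufa4 between cells with and without AA467197 was 0.677 and 0.578 in the control libraries, below all 17 other oxidative phosphorylation genes (lowest 0.848 and 0.845), and 0.659 and 0.819 in the LNP-Sirpa libraries. This is what the hypothesis predicted. The share of cells with AA467197 was 19.5%, 19.4%, 64.0% and 76.0%. The test of a general fall of these transcripts was chosen after the result was seen: the other 17 genes had a median of -0.10, 8.1% of the Ndufa4 value, which argues against it.

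The 2 LNP-Sirpa libraries differed in type I interferon genes. The median ratio of LNP-Sirpa replicate 1 to replicate 2 was 2.89 in monocyte/macrophage-like, 1.71 in dendritic-like, 1.92 in neutrophil-like, 2.69 in CD8 T-like, 2.77 in regulatory T-like and 3.97 in NK-like cells, and between control replicates 1 and 2 it was 1.09, 1.0, 1.24, 1.07, 1.14 and 1.16. Cox5a had 133 and 272 CPM in the control and 551 and 488 CPM in the LNP-Sirpa libraries in monocyte/macrophage-like cells (1.52 ± 0.36, adjusted p = 0.0642).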
